A study of Homo sapiens with 18 samples.

How the data were processed

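RNA was profiled in H1 human embryonic stem cells carrying a control shRNA or an shRNA against NAT10, at 0, 1.5 and 3.5 h of actinomycin D, with 3 libraries in each of the 6 groups. Per the labels' protocols, shRNAs were delivered by lentivirus with a GFP marker, GFP-positive cells were enriched and expanded under puromycin, total RNA was extracted with TRIzol, and ERCC spike-in RNA was added once the RNA had been purified. Polyadenylated RNA was then captured on oligo(dT) beads and sequenced on a BGISEQ instrument. Because the spike-in followed purification, it does not measure polyadenylated RNA per cell. It measures polyadenylated RNA per amount of purified RNA only if that amount was equal between libraries, which is not known here.

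The authors deposited raw read counts per gene and per ERCC transcript, with one column per library. The submitters' processing notes name fastp 0.21.1, HISAT2 2.2.1, SAMtools 1.12, featureCounts 2.0.3 and the human genome build hg38. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, are uncertain. The authors also deposited a signal per gene and library, which was found from its values to be the count multiplied by 1 factor per gene and 1 factor per library. The largest relative deviation from that product was 6.2e-15, and for 77.3% of 12698 genes the gene factor lay within 5% of the exonic length. The authors' library factors followed the summed ERCC counts to within 0.17 on the log2 scale. In the same table the authors deposited half-lives in hours (a unit of its own, neither a count nor a ratio), 1 per gene and genotype, with no error. A least-squares fit of an exponential decay to the 9 levels of a genotype gave 100% of the deposited half-lives to within 1%. The last column deposited by the authors is the log2 ratio of the knockdown to the control half-life.

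The count table held 61952 entries, of which 92 were ERCC transcripts and 61860 were genes. Gene symbols were found for 58425 genes, and 58308 gene identifiers were in GENCODE v29, the annotation used here for coordinates, gene types and GC content. ERCC transcripts with at least 10 counts in every library numbered 27, and the ERCC share of a library's counts ran from 0.0857% to 0.544%. Totals ran from 15037492 to 15519197 counts per library, ERCC included. The filterByExpr function of edgeR left 16760 genes and removed 45100.

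Genes were tested with edgeR's quasi-likelihood F test on the counts, with Benjamini-Hochberg adjustment and a threshold of 0.05, in one fit to all 18 libraries. The knockdown was compared with the control at each time under TMM scaling, which sets each gene against the typical transcript. Changes over time and decay slopes were scaled to the summed ERCC counts, since blocking transcription lowers most transcripts together. The decay slope is the change of the log2 level per hour over the 3 time points, and its difference between genotypes is the genotype-by-time term. A fitted half-life is 1 divided by the negative of that slope, for genes whose slope was negative in both genotypes. The common biological coefficient of variation was 6.3% under TMM and 16.3% under ERCC scaling. The ratio of summed gene counts to summed ERCC counts was compared between groups with exact two-sided permutation tests. Errors of levels are SDs over libraries. Errors of log2 changes and slope differences are approximate SEs, the absolute change divided by the square root of the test's F statistic. Levels are TMM-scaled CPM, a count relative to the scaled library total, and the percentage of transcript left is the ERCC-scaled level relative to the mean of the same genotype at 0 h.

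Gene lists numbered 23, of which 21 had at least 5 measured members and were tested with camera (preset correlation 0.01, and again with an estimated one) and fry on voom-weighted values, with Benjamini-Hochberg adjustment over the lists. The samples, tests, lists and rule for named genes were chosen before the data were examined. The rule takes NAT10, POU5F1, SOX2, NANOG and ANP32B whatever their values, the 8 largest rises and 8 largest falls per main comparison, and the 3 members of each list with the smallest p, of which the text gives those of the lists it describes. Some genes that the rule takes at 0 h are not reported here. The largest rises and falls were taken among genes that passed the test, had a symbol, a mean of at least 5 CPM and replicate values that did not overlap (for the slope, a negative slope in both genotypes). No per-gene test was made on the authors' half-lives, which have 1 value per genotype.

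Alternatives were DESeq2's size factors and its Wald test, the other scaling, no filter on low counts, a fit to the compared groups only, the replicate number as a block, each library left out in turn, a minimum change, and other time models. Chosen after seeing the data were TMM over the ERCC transcripts, the authors' library factors, removal of a GC trend, the lists without the first knockdown library at 0 h, naive markers with the count filter on control libraries alone, and list tests with an estimated correlation under TMM for the changes over time. Other splits of the libraries were counted in the same fits.

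The procedures were tested on simulated counts in which 200 of 16760 genes were changed. For the comparison at 0 h, edgeR recovered 71.6% of 1.5-fold, 86.6% of 2-fold and 98.5% of 4-fold changes with 3.39% false calls, and DESeq2 recovered 65.7%, 83.6% and 98.5% with 5.17% false calls. For the slope, differences of 0.2 and 0.4 per hour on the log2 scale were recovered for 34% and 81% of genes with exact spike-in factors, and for 1% and 76% once the spike-in carried an error with an SD of 0.215 on the log2 scale. In the first of these 0.862% of the calls were false. Camera called a raised list and did not call an unchanged one. The simulated genes were drawn independently, so this does not test the preset correlation.

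Replicate libraries of each group were compared by a chi-square test over genes, and no pair was close enough to count as 1 library. Calculations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.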

Results

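The series followed the decay of transcripts in H1 cells, an established human embryonic stem cell line, with normal or lowered NAT10. NAT10 is the RNA acetyltransferase that makes N4-acetylcytidine (ac4C). The series title sets out the question of whether transcript half-lives depend on this mark. Transcription was blocked with actinomycin D, and polyadenylated RNA was counted at 0, 1.5 and 3.5 h in 3 libraries per genotype and time, 18 in all. Libraries held 15037492 to 15519197 counts. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

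NAT10 itself (ENSG00000135372, chromosome 11, 34105602 to 34147670, GRCh38) was low in every knockdown library. At 0 h its level was 210 ± 1.13 CPM in control and 21.9 ± 1.94 CPM in knockdown (SD, n = 3 each), a log2 fold change of -3.26 ± 0.064 (edgeR quasi-likelihood test, adjusted p = 2.81e-21). The log2 fold change was -3.63 ± 0.066 at 1.5 h and -3.67 ± 0.066 at 3.5 h. Over all times the 9 control libraries lay between 209 and 250 CPM and the 9 knockdown libraries between 17.2 and 24.1 CPM.

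**Figure D1:**
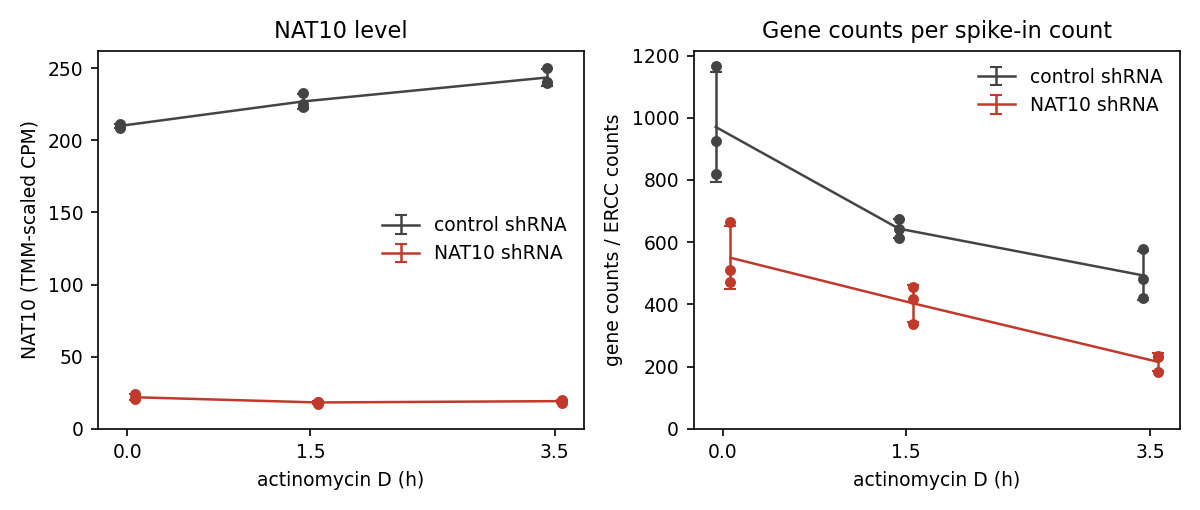
The left panel plots NAT10 in TMM-scaled CPM and the right panel the ratio of gene counts to ERCC counts, both against hours of actinomycin D, with 1 point per library and the mean and SD of 3 libraries per group. NAT10 stayed between 17.2 and 24.1 CPM in knockdown libraries, and the ratio went from 970 to 493 in control and from 550 to 216 in knockdown.

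At 0 h, before the block, p53 targets and naive pluripotency markers were higher in knockdown cells, relative to the typical transcript. Genes of ribosome biogenesis, DNA replication and chromatin regulation were lower. CNN1, the actin-binding protein calponin of smooth muscle (chromosome 19, 11538717 to 11550323), rose from 9.07 ± 0.772 to 133 ± 20.5 CPM (SD, n = 3 each), a log2 fold change of 3.87 ± 0.104 (adjusted p = 1.76e-18). BTG2, an antiproliferative target of p53, rose by 3.78 ± 0.184 (adjusted p = 4.17e-14). ALPG, the germ cell alkaline phosphatase, rose by 4.60 ± 0.249, the adaptor gene SH2D3C by 4.36 ± 0.268. The transcription factor gene CREB5 rose by 3.65 ± 0.147 and the cyclin gene CCNA1 by 3.61 ± 0.14. MAB21L4 had 2 counts in the 3 control libraries and 469 in the 3 knockdown libraries, a ratio of 212 with a 95% counting interval of 58.3 to 1760.

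The chromatin remodeller CHD7 (chromosome 8, 60678778 to 60868028) fell from 199 ± 8.43 to 42.5 ± 1.58 CPM at 0 h, a log2 fold change of -2.23 ± 0.061 (adjusted p = 1.85e-18). GABARAPL2, which acts in autophagosome formation, fell by 2.25 ± 0.104 on the log2 scale, and ZDHHC22, of the protein palmitoyltransferase family, by 2.25 ± 0.077. HSD11B2, which inactivates cortisol, fell from 17.7 ± 4.55 to 3.85 ± 0.683 CPM. The long noncoding RNA D21S2088E fell from 46.5 ± 2.06 to 5.74 ± 0.827 CPM. The mitochondrial phenylalanine tRNA gene MT-TF fell from 33.7 ± 0.5 to 2.73 ± 0.504 CPM, though a tRNA is a poor target of oligo(dT) capture. The metallothionein gene MT2A, one of a family of near-identical genes, fell by 2.48 ± 0.34 on the log2 scale (adjusted p = 1.75e-06), from control libraries that differed widely (72.9 ± 56.9 CPM).

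Genes of the pluripotent state moved in different directions at 0 h. Of 30 core pluripotency genes 18 fell and 3 rose (18 and 3 also when adjusted over the list alone), with a median log2 fold change of -0.33 (camera adjusted p = 0.00176, and adjusted p = 0.014 with an estimated correlation). SOX2 (chromosome 3, 181711924 to 181714436), a core pluripotency factor, fell from 61.5 ± 1.04 to 44.0 ± 4.03 CPM (log2 fold change -0.48 ± 0.084, adjusted p = 3.92e-05). TRIM71, an RNA-binding protein of early development, fell by 0.62 ± 0.049 on the log2 scale. FGF2, a growth factor that maintains these cells, rose by 1.38 ± 0.081. POU5F1, which has several processed pseudogenes, stood at 397 ± 14.2 and 390 ± 30.7 CPM (log2 fold change -0.03 ± 0.053, adjusted p = 0.711), and NANOG at 19.2 ± 1.71 and 20.4 ± 2.92 CPM (0.09 ± 0.097, adjusted p = 0.458). Neither of these passed the test, but both passed as lower under ERCC scaling, where the median of all genes was -0.71. There POU5F1 fell by 0.70 (adjusted p = 6.48e-04) and the sign of NANOG turned (-0.56, adjusted p = 0.0102). Of 10 measured markers of naive pluripotency 9 rose (9 when adjusted over the list alone), with a median of 2.15 (camera adjusted p = 5.08e-05, and adjusted p = 0.0105 with an estimated correlation). Of 15 matched markers only these 10 passed the count filter, and 4 did so in the control libraries alone, of which 3 rose, with a median of 1.05. The rise itself thus helped to choose the members, while with no filter 10 of the 15 rose and 0 fell. Among these the transcription factor genes KLF5 and TFAP2C rose from 1.02 ± 0.191 to 4.74 ± 0.855 CPM and from 2.54 ± 0.75 to 8.29 ± 1.2 CPM.

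The targets of p53, a list of growth arrest, repair and death genes, rose together. Of 30 measured members 27 rose and 2 fell (28 and 2 when adjusted over the list alone), with a median of 1.16 (camera adjusted p = 5.25e-16, and adjusted p = 5.2e-05 with an estimated correlation). Under ERCC scaling 17 rose and 3 fell. PLK2, a kinase of the stress response, rose by 2.47 ± 0.116 on the log2 scale and MDM2, the ubiquitin ligase that degrades p53, by 1.49 ± 0.086. Markers of fibroblasts and stroma rose in 10 of 14 cases and fell in 3 (10 and 3 over the list alone, camera adjusted p = 1.72e-04, and adjusted p = 0.0499 with an estimated correlation), but 5 rose and 4 fell under ERCC scaling. COL1A1, a chain of type I collagen, went from 188 ± 9.27 to 980 ± 165 CPM, and TAGLN, an actin-binding protein, from 93.4 ± 4.42 to 331 ± 43.7 CPM. The neural ectoderm list lay to the higher side but did not pass (5 higher and 3 lower of 10, the same when adjusted over the list alone, camera adjusted p = 0.0582, and 0.142 with an estimated correlation). It did pass, to the higher side of all genes, under ERCC scaling and without knockdown replicate 1 at 0 h (camera adjusted p = 0.0211 and 0.0474). In it MAP2, a neuronal microtubule protein, rose by 3.01 ± 0.119 and NES, the intermediate filament protein nestin, by 1.01 ± 0.061 (for NES adjusted p = 0.0937 under ERCC scaling, where the list had 2 higher and 4 lower). The mesoderm list did not pass either (2 higher and 2 lower of 6, the same over the list alone, camera adjusted p = 0.774). Definitive endoderm and trophoblast had 4 measured members each and were not tested. Of 18 matched fibroblast markers 14 passed the count filter, and of 24 matched neural ectoderm markers 10 did. Whether a rise helped to choose these members was not tested.

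Genes of ribosome production and of the cell cycle fell at 0 h. Of 47 ribosome biogenesis genes 38 fell (39 when adjusted over the list alone), with a median of -0.30 (camera adjusted p = 3.6e-08, and adjusted p = 0.0105 with an estimated correlation), among them UBTF, which activates RNA polymerase I (-0.52 ± 0.051), and UTP20, a small-subunit processome protein (-0.54 ± 0.053). Of 75 cytosolic ribosomal protein genes, many with pseudogene copies, 49 fell and 2 rose (49 and 2 over the list alone), with a median of -0.23 (camera adjusted p = 1.04e-07, but adjusted p = 0.104 with an estimated correlation). RPL12 fell by 0.51 ± 0.039 and RPL4 by 0.47 ± 0.038. DNA replication genes fell in 28 of 35 cases (29 over the list alone, camera adjusted p = 2.89e-07, and adjusted p = 0.0105 with an estimated correlation). The replication licensing factor CDC6 stood at -0.56 ± 0.049 and UHRF1, which recruits the maintenance DNA methyltransferase, at -0.99 ± 0.091. Mitosis genes fell in 27 of 34 cases (28 over the list alone, camera adjusted p = 8.46e-09, but adjusted p = 0.0834 with an estimated correlation). The proliferation marker MKI67 stood at -0.97 ± 0.049 and the survivin gene BIRC5 at -0.68 ± 0.054.

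Chromatin regulators fell in 28 of 40 cases and rose in 3 (30 and 3 over the list alone, camera adjusted p = 1.51e-06, and adjusted p = 6.95e-04 with an estimated correlation). TET1, a methylcytosine dioxygenase, fell by 1.59 ± 0.062, and the histone chaperone gene ANP32A by 1.25 ± 0.062. ANP32B, of the same family (chromosome 9, 97983361 to 98015943), fell from 171 ± 3.8 to 107 ± 4.66 CPM (log2 fold change -0.68 ± 0.054, adjusted p = 2.7e-10). RNA modification enzymes, a list that includes NAT10, fell in 18 of 31 cases and rose in 2 (18 and 2 over the list alone, camera adjusted p = 0.00133, and adjusted p = 0.012 with an estimated correlation). The m6A writer subunit VIRMA stood at -0.84 ± 0.068 and the m6A reader YTHDF2 at -0.75 ± 0.064. Cholesterol synthesis genes fell in 17 of 25 cases and rose in 1 (17 and 1 over the list alone, camera adjusted p = 9.14e-05, and adjusted p = 0.0343 with an estimated correlation). The synthase gene HMGCS1 stood at -0.88 ± 0.072 and the epoxidase SQLE at -0.71 ± 0.066. Interferon response genes rose in 12 of 20 cases and fell in 2 (12 and 2 over the list alone, camera adjusted p = 0.00654, and adjusted p = 0.0343 with an estimated correlation), but 3 rose and 7 fell under ERCC scaling. HERC5, the ligase for ISG15, rose by 1.34 ± 0.072. Of 30 matched interferon genes only 20 passed the count filter, and whether the rise helped to choose them was not tested.

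Other lists moved less evenly at 0 h. The list of 13 genes encoded by mitochondrial DNA, which does not hold MT-TF, included 9 that fell and 1 that rose (9 and 1 over the list alone, camera adjusted p = 0.00133, but adjusted p = 0.112 with an estimated correlation). The cytochrome oxidase gene MT-CO1 stood at -0.78 ± 0.049. Nuclear genes of oxidative phosphorylation fell in 25 of 54 cases and rose in 2 (25 and 2 over the list alone, camera adjusted p = 0.00488, but adjusted p = 0.103 with an estimated correlation). The mRNA decay machinery fell in 25 of 52 cases and rose in 7 (26 and 8 over the list alone, camera adjusted p = 0.00561, but adjusted p = 0.119 with an estimated correlation). Of 425 C2H2 zinc finger genes 148 fell and 53 rose (143 and 51 over the list alone, camera adjusted p = 0.0282, but adjusted p = 0.408 with an estimated correlation). Immediate early and AU-rich genes rose in 16 of 36 cases and fell in 8 (16 and 8 over the list alone, camera adjusted p = 0.0388, but adjusted p = 0.0834 with an estimated correlation), and under ERCC scaling 5 rose and 17 fell. ATF3 rose by 2.64 ± 0.137 and JUN by 3.07 ± 0.16 in this list, both transcription factors of the stress response. Of the 41 matched genes of this list 36 passed the count filter, and whether the rise helped to choose them was not tested. The unfolded protein and integrated stress response list was split (10 higher and 13 lower of 28, the same over the list alone, camera adjusted p = 0.503), with the chaperone gene HSPA5 at -0.92 ± 0.042 and the lipoprotein receptor gene VLDLR at 1.25 ± 0.084. Glycolysis genes were split as well (6 higher and 9 lower of 21, 6 and 10 over the list alone, camera adjusted p = 0.69).

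**Figure D2:**
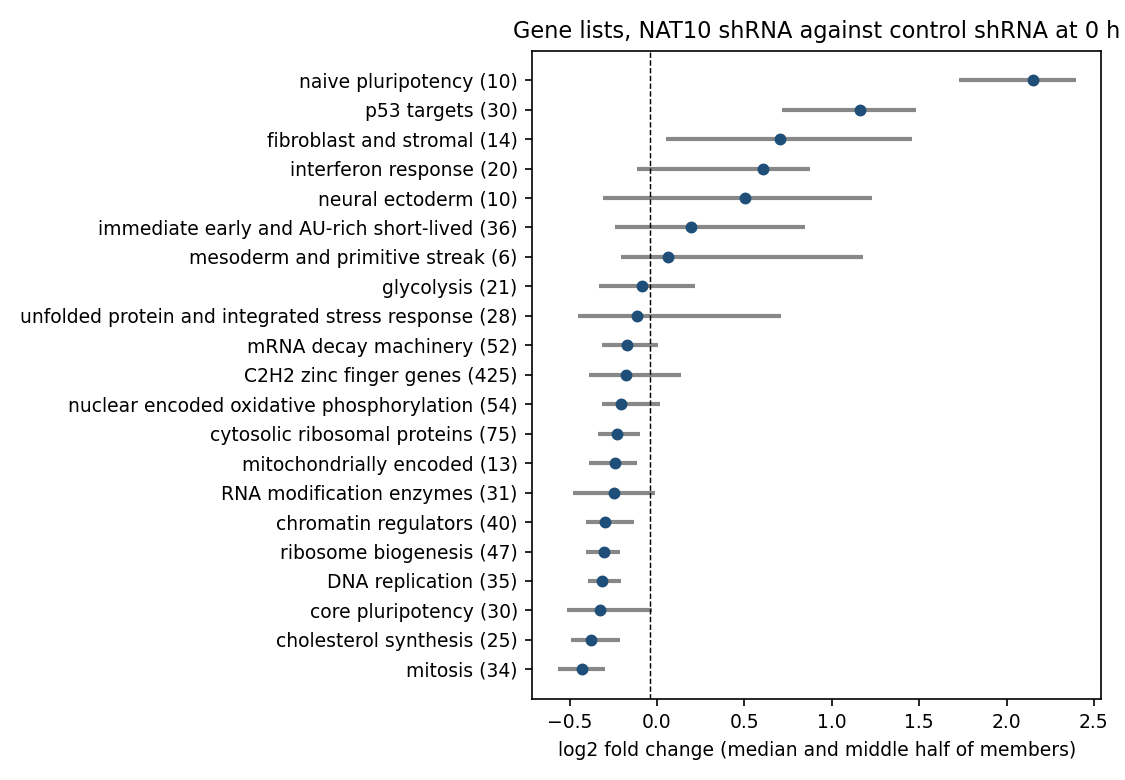
Each point is the median log2 fold change of a gene list at 0 h, knockdown against control under TMM scaling, the bar spans the interquartile range of its members, and the dashed line is the median of all genes (-0.04). The naive pluripotency and p53 medians stood at 2.15 and 1.16 and the mitosis median at -0.43, while under ERCC scaling the medians of the neural ectoderm, mesoderm, immediate early and interferon lists turned negative (-0.14, -0.61, -0.46 and -0.06) with an all-gene median of -0.71.

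In all, 3992 genes were higher and 4736 lower in knockdown at 0 h of 16760 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 45.7% of the calls being higher, with 1539 and 427 of them changed at least 2-fold. A fit to the 0 h libraries alone turned the balance, with 3374 higher and 2975 lower (53.1% higher), as did no count filter (4358 and 4249, 50.6% higher). Scaling to the spike-in moved the median of all genes from -0.04 to -0.71 and gave 936 higher and 10748 lower genes, 8.0% higher, so the directions above are relative to the typical transcript. Under it 52 of 54 oxidative phosphorylation genes, 48 of 52 genes of mRNA decay, 28 of 31 RNA modification enzymes, 16 of 21 glycolysis genes and 328 of 425 zinc finger genes fell. Knockdown replicate 1 at 0 h stood apart from replicates 2 and 3 (chi-square per degree of freedom 15.2 and 21.7, against 2.14 between those 2). Without it 27 of 30 p53 targets and 10 of 10 naive markers were higher, and 54 of 75 ribosomal protein genes, 39 of 47 ribosome biogenesis genes, 26 of 35 replication genes and 29 of 34 mitosis genes were lower. At 1.5 h 4764 genes were higher and 4384 lower (1375 and 8331 under ERCC scaling), and at 3.5 h 5873 were higher and 4423 lower (789 and 12015 under ERCC scaling). SOX2, lower at 0 h, was higher by 1.48 ± 0.1 on the log2 scale at 3.5 h (adjusted p = 9.87e-12).

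The total of polyadenylated RNA per spike-in fell in both genotypes. In control the ratio of gene counts to ERCC counts was 970 ± 177 at 0 h, 644 ± 29.8 at 1.5 h and 493 ± 78.3 at 3.5 h (SD, n = 3 each). In knockdown it was 550 ± 101, 403 ± 59.5 and 216 ± 28.5. Knockdown stood at 56.7% of control at 0 h (exact two-sided permutation test, p = 0.1, the smallest p that 3 against 3 libraries allow). At 1.5 h the ratio was 66.3% of the 0 h value in control and 73.3% in knockdown, and at 3.5 h it was 50.8% and 39.2%. The order of these means turned between the times, but the turn was not tested. The slopes were -0.27 and -0.39 per hour on the log2 scale, and their difference did not pass the test (two-sided permutation test, p = 0.143).

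Transcripts of TENT5B, a noncanonical poly(A) polymerase (chromosome 1, 27005020 to 27012836), fell furthest among the named genes in control cells, to 1.75 ± 0.69% of the 0 h level at 3.5 h (SD, n = 3; log2 fold change -5.86 ± 0.259, adjusted p = 6.82e-109). HPS6, CCDC71, RNF139, INTS5, IRF2BP1, DDX28 and RIOX1 were left at 2.49% to 3.12%. The pluripotency genes PRDM14, ZFP42 and SOX2 were left at 3.98 ± 0.607%, 7.51 ± 1.3% and 9.77 ± 2.43%, and NANOG at 20.7 ± 1.74%. ANP32B was left at 69.4 ± 11.5% (log2 fold change -0.53 ± 0.195, adjusted p = 0.0094) and NAT10 at 53.1 ± 8.24% (-0.91 ± 0.197), while both lay above their 0 h level relative to the typical transcript under TMM scaling (0.60 and 0.21). POU5F1 was at 79.0 ± 13.1%, which did not pass the test (adjusted p = 0.0907, but 0.0309 without control replicate 2 at 3.5 h), and under TMM scaling its log2 change was 0.78.

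A small group of transcripts rose in control cells during the block. H2AC6, a replication-type histone H2A gene of a family with near-identical members (chromosome 6, 26124145 to 26139116), reached 281 ± 46.4% of its 0 h level at 3.5 h (log2 fold change 1.49 ± 0.267, adjusted p = 5.82e-08). Only its polyadenylated transcripts were captured, with 73 counts in the 3 control libraries at 0 h and 398 at 3.5 h. OPN3, an opsin, reached 225 ± 13.2%, the sulfatase gene SULF1 230 ± 29.3%, and the metallothionein genes MT1G and MT1X, which share near-identical sequence, 226 ± 40.8% and 213 ± 39.9%. RAB37, ITGA2B and SYT12 each reached 188%. In knockdown cells these 8 genes were left at 28.4% to 47.4%.

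By list, the C2H2 zinc finger genes fell further in control than the median of all genes (-1.14), with 415 of 425 fallen (418 when adjusted over the list alone) and a median of -1.94. So did ribosome biogenesis genes (46 of 47, 46 over the list alone, median -1.72) and RNA modification enzymes (31 of 31, 31 over the list alone, median -1.63). Relative to the typical transcript under TMM scaling 307 zinc finger genes fell and 20 rose, 32 ribosome biogenesis genes fell and 8 rose, and 22 RNA modification enzymes fell and 4 rose. ZNF48 and ZNF281 were left at 3.77 ± 0.362% and 6.04 ± 1.44%. All 30 p53 targets fell (30 over the list alone, median -2.02), against 20 fallen and 5 risen under TMM scaling (median -0.90), with the death effector BBC3 left at 6.23 ± 2.26%. Cytosolic ribosomal proteins fell in 52 of 75 cases (46 over the list alone) with a median of -0.45, but under TMM scaling all 75 rose, with a median of 0.68. Oxidative phosphorylation genes did the same, with 37 of 54 fallen (37 over the list alone, median -0.51) and 49 risen under TMM scaling. The camera tests of these 6 lists had adjusted p of 1.07e-10, 2.67e-09, 3.61e-07, 9.73e-04, 1.7e-06 and 3.45e-04 in that order, but adjusted p = 0.69 for each with an estimated correlation. In these tests ribosomal proteins and oxidative phosphorylation genes lay to the higher side of all genes, having fallen less. The other lists lay to the lower side. With an estimated correlation under TMM scaling the adjusted p were 0.03, 0.03, 0.0109, 0.03, 0.0109 and 0.00292.

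In control 13590 genes fell and 99 rose from 0 to 3.5 h (ERCC scaling, edgeR quasi-likelihood, median log2 fold change -1.14), against 5804 and 5301 relative to the typical transcript under TMM scaling. In knockdown 16311 fell, with a median of -1.47, and 0 rose, with 0 at an unadjusted p under 0.05 and 0 by DESeq2, against 3814 and 4213 under TMM scaling. The 99 rises in control became 62 without control replicate 2 at 0 h. ANP32B no longer passed without control replicate 1 at 0 h or at 3.5 h (log2 fold change -0.36 and -0.44, adjusted p = 0.101 and 0.0548).

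**Figure D3:**
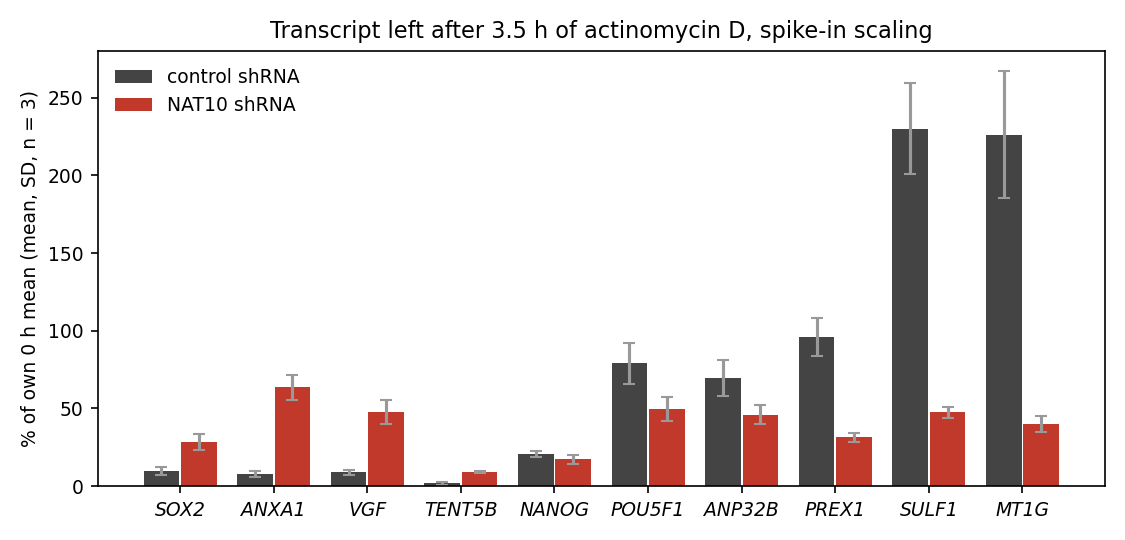
Bars give the mean percentage of transcript left at 3.5 h relative to the same genotype at 0 h, scaled to the spike-in, for 10 named genes in control and knockdown, with error bars of 1 SD over 3 libraries. ANXA1 was left at 8.09% in control and 63.7% in knockdown and PREX1 at 95.9% and 31.6%, while under TMM scaling POU5F1 and ANP32B in control lay above their 0 h level (log2 change 0.78 and 0.60).

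Decay was slower in knockdown for ANXA1, a phospholipid-binding annexin (chromosome 9, 73151757 to 73170393). Its transcript was left at 8.09 ± 1.96% in control and 63.7 ± 8.02% in knockdown at 3.5 h (SD, n = 3 each), a slope difference of 0.85 ± 0.091 per hour on the log2 scale (adjusted p = 5.24e-17). VGF, a neuropeptide precursor, was left at 9.05 ± 1.59% and 47.7 ± 7.62%, and TENT5B at 1.75 ± 0.69% and 9.04 ± 0.728%. The slope difference was 0.68 ± 0.114 for ADM, the gene of the vasodilator adrenomedullin, and 0.62 to 0.72 for DDX28, INTS5, B3GNT2 and CCDC71. SOX2 was left at 9.77 ± 2.43% in control and 28.6 ± 5.16% in knockdown (slope difference 0.44 ± 0.082, adjusted p = 1.54e-05), and PRDM14, a regulator of germ cell and stem cell fate, at 3.98 ± 0.607% and 14.0 ± 2.18% (0.52 ± 0.089, adjusted p = 1.34e-06). The mitotic kinases PLK1 and AURKA (0.46 ± 0.085 and 0.40 ± 0.087), the stress factor XBP1 (0.54 ± 0.089) and YTHDF2 (0.42 ± 0.085) also decayed more slowly in knockdown. TENT5B, DDX28, INTS5 and CCDC71 were also among the 8 largest falls in control.

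Decay was faster in knockdown for CYP1B1, a cytochrome P450 (slope difference -0.51 ± 0.098, adjusted p = 2.33e-05), COPG2IT1 (-0.51 ± 0.097), the potassium channel gene KCNC4 (-0.49 ± 0.09), LYNX1, which modulates nicotinic receptors (-0.49 ± 0.097), the neuropeptide receptor gene ADCYAP1R1 (-0.48 ± 0.092), SH3PXD2A (-0.48 ± 0.088), PROM2 (-0.48 ± 0.096) and PREX1 (-0.48 ± 0.087). PREX1, a Rac exchange factor, was left at 95.9 ± 12.3% in control and 31.6 ± 2.91% in knockdown. BST2, an antiviral membrane protein, and PDGFRB, a growth factor receptor, stood at 150 ± 28.1% and 132 ± 25.4% in control against 39.2 ± 4.85% and 35.6 ± 5.91% in knockdown. NAT10 itself was left at 53.1 ± 8.24% and 30.8 ± 4.56% (-0.23 ± 0.08, adjusted p = 0.0409). Since the shRNA is directed against this transcript, the call cannot be told apart from a direct action of the shRNA. That call was lost, with adjusted p from 0.0533 to 0.153, when 1 library was left out among control replicates 2 and 3 at 0 h, 1 and 3 at 1.5 h and 2 and 3 at 3.5 h, or knockdown replicates 1 at 0 h and 2 and 3 at 3.5 h. The estimates there stayed at -0.189 to -0.235. The call was lost as well with no count filter (-0.23, adjusted p = 0.0881), with only the 1.5 and 3.5 h libraries (-0.27, 0.0773) and with a GC trend removed (-0.21, 0.0557), and it held under TMM scaling (-0.11, 0.00805). NANOG (-0.07 ± 0.087, adjusted p = 0.597), POU5F1 (-0.20 ± 0.078, adjusted p = 0.0624) and ANP32B (-0.18 ± 0.079, adjusted p = 0.1) did not pass the test, and for NANOG the sign turned under TMM scaling (0.04). POU5F1 and ANP32B did pass without control replicate 1 at 0 h (adjusted p = 0.00865 and 0.0149) or knockdown replicate 3 at 0 h (0.0315 and 0.0372), with only the 1.5 and 3.5 h libraries (0.0148 and 0.00803) and under DESeq2's size factors (0.00208 and 0.0263). POU5F1 passed as well under TMM scaling (slope difference -0.08, adjusted p = 0.00618), with DESeq2's Wald test (0.0367) and with the authors' library factors (0.0303).

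Among the lists, 6 of 47 ribosome biogenesis genes decayed more slowly and 1 faster in knockdown (6 and 1 when adjusted over the list alone, camera adjusted p = 2.31e-04, but adjusted p = 0.814 with an estimated correlation). Of 34 mitosis genes 5 decayed more slowly and 0 faster (5 and 0 over the list alone, camera adjusted p = 0.00281, but adjusted p = 0.814 with an estimated correlation). Under TMM scaling 30 ribosome biogenesis genes were slower and 1 faster, and 16 mitosis genes slower and 1 faster. MPHOSPH10 and UTP14A, both of the small-subunit processome, had slope differences of 0.46 ± 0.091 and 0.34 ± 0.086. Ribosomal proteins lay to the faster side by the list test (camera adjusted p = 4.08e-05, but adjusted p = 0.814 with an estimated correlation), and only 4 of 75 were called faster, 0 when adjusted over the list alone and 10 under TMM scaling. RPL3 was among them at -0.25 ± 0.077, a call lost without control replicate 2 or 3 or knockdown replicate 3 at 3.5 h (adjusted p = 0.0685, 0.0503 and 0.054). Its estimates there were -0.214, -0.243 and -0.224. In control the medians of the fall were -1.72 for ribosome biogenesis, -1.29 for mitosis and -0.45 for ribosomal proteins, against -1.14 for all genes. Slopes spread less over genes in knockdown (SD 0.14, against 0.262 in control). Such a narrowing would move fast-falling lists to the slower side and slow-falling lists to the faster side. These list results therefore cannot be told apart from the narrowing.

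In all, 403 genes decayed more slowly and 1838 faster in knockdown (ERCC scaling, edgeR quasi-likelihood, adjusted p under 0.05), 18.0% slower, against 3439 and 1863, 64.9% slower, relative to the typical transcript under TMM scaling. Under ERCC scaling the faster calls came from the later window. The difference at 1.5 h gave 0 faster and 4 slower genes (37 and 705 at an unadjusted p under 0.05, 0 and 2 by DESeq2, median 0.17), and the 1.5 and 3.5 h libraries alone gave 4699 faster and 261 slower. In the fit to all libraries the change from 1.5 to 3.5 h gave 3130 faster and 187 slower genes. Under TMM scaling that change gave 1933 faster and 3064 slower. The ERCC-scaled count depended on single libraries. Faster genes numbered 4298 without control replicate 1 at 0 h, 2796 without knockdown replicate 3 at 0 h, 735 and 990 without control replicates 2 and 3 at 3.5 h and 909 without knockdown replicate 3 at 3.5 h. Slower genes numbered 232 and 221 without control replicates 1 and 3 and 266 without knockdown replicate 2 at 3.5 h. With only the 1.5 and 3.5 h libraries SOX2 no longer passed (adjusted p = 0.184).

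**Figure D4:**
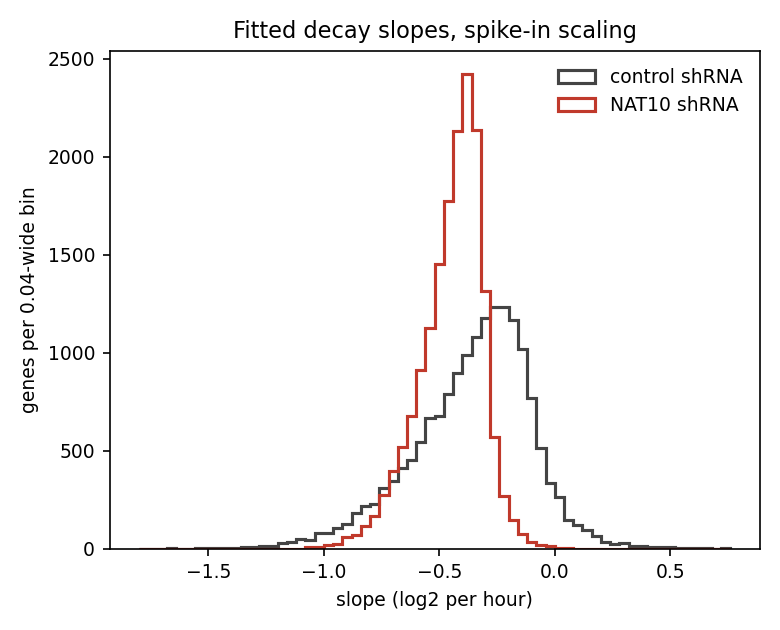
The histogram gives the number of genes per bin of fitted decay slope (log2 per hour, ERCC scaling) in control and knockdown, over 16760 genes. The SD of the slopes was 0.262 in control and 0.14 in knockdown, and the medians were -0.32 and -0.42.

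Half-lives fitted from the slopes had a median of 2.96 h in control (quartiles 1.92 and 4.87 h) and 2.33 h in knockdown (1.88 and 2.80 h) over 15882 genes. They were longer in knockdown for 4578 genes and shorter for 11304. SOX2 went from 1.05 to 1.94 h, ANXA1 from 0.948 to 4.90 h and NANOG from 1.55 to 1.39 h. POU5F1 went from 10.9 to 3.41 h and ANP32B from 6.92 to 3.06 h, control values well beyond the last time point. The difference of the medians, -0.632 h with a jackknife error of 0.609 h, was about the size of its error and turned positive under TMM scaling (4.26 h, over 6257 genes).

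The authors' deposited table gave a median half-life of 3.05 h in control and 2.55 h in knockdown over 12306 genes, with 4007 longer and 8299 shorter in knockdown and a median log2 ratio of -0.24. In the authors' deposited table SOX2 went from 0.867 to 1.96 h, ANXA1 from 1.63 to 6.32 h and VGF from 1.46 to 3.75 h. There POU5F1 went from 11.6 to 3.56 h, ANP32B from 6.88 to 3.35 h and NAT10, the target of the shRNA, from 3.84 to 1.98 h. Half-lives at least 1.5-fold longer were listed for 349 genes and 1.5-fold shorter for 3883 in the authors' deposited table, which gives no error per gene. Its log2 ratios had a Spearman correlation of 0.964 with the ratios fitted here over 12210 genes.

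The knockdown's effect on the fall from 1.5 to 3.5 h was set against its effect on levels at 0 h, in libraries that the values do not share. Across 16760 genes the Spearman correlation was -0.17 with a jackknife error of 0.038 (Pearson -0.19), and genes are not independent replicates. The sign means that genes higher in knockdown at 0 h tended, weakly, to fall further there. SOX2 went with it, with a log2 fold change of -0.48 at 0 h, 0.52 at 1.5 h and 1.48 at 3.5 h. With slopes over all 3 times, which share the 0 h libraries, the correlation was -0.19 and the covariance -0.0324. Simulated genes with no knockdown change, drawn independently, gave a correlation of -0.60 and a covariance of -0.00995. Since none of them truly changed, their correlation is no chance value for the real one.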

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

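Among the tests below, the removal of a GC trend and the test of spike-in error were chosen only after a result was seen. So were the split count relative to the typical transcript and the look at which splits were large.

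The difference in decay between genotypes is given here because the genotype-by-time term was itself tested, with the same scaling in both genotypes: 2241 genes differed in slope and 2043 in the fall from 0 to 3.5 h. Single genes with such a difference were ANXA1 (0.85 per hour on the log2 scale, knockdown minus control), SOX2 (0.44), H2AC6 (-0.92) and MT1G (-0.74).

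For the 2241 slope calls, 7 of 100 splits of the libraries within each time gave as many, the real one included, and the highest other gave 9999. Relative to the typical transcript the real split called 5302 genes, again 7 of 100 gave as many, and the highest other called 6145. A split that calls several times the real count points to a structure of the samples: all 7 kept the genotypes apart at 3.5 h, and so carried the difference between genotypes at that time. With 3 against 3 libraries about 1 in 10 splits do so by design, so the count of 7 decides nothing about chance. The 93 splits that mixed the genotypes at 3.5 h gave at most 0 calls under either scaling (edgeR, adjusted p under 0.05), but the 10 splits of that time are too few for a share under 0.05. An error of the spike-in shared by all genes of a library may add to the slope calls: the slope of the gene-to-spike-in ratio differed between genotypes with a permutation p of 0.143, so the general shift towards faster decay cannot be told apart from such an error. A true difference in decay through NAT10 stays open as well.

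For the 8728 calls at 0 h, 10 splits are too few for a share under 0.05, and the highest other called 1316. The same holds at 1.5 h (9148, highest other 0), at 3.5 h (10296, highest other 0), for the fall in control (13689, highest other 0) and for the fall in knockdown (16311, highest other 1). GC-rich genes were low in knockdown replicate 1 at 0 h, but 92% of the calls were made again in the same direction without that library, and 97.2% with a GC trend removed from each library. Both values argue against that library and the GC trend as the whole cause. The knockdown of NAT10 stays open as a hypothesis, since it cannot be separated here from other differences between the cell populations.

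The spread of decay slopes was narrower in knockdown, with an SD ratio of 0.534. Counting noise of low genes would not account for it, since among 4213 genes with at least 50 CPM the highest ratio over the fits that left out 1 library was 0.542, and a GC trend would not either, since the highest ratio with the trend removed was 0.558. Transcription that went on in knockdown cells under actinomycin D could also narrow the slopes. In that case the gap between short-lived and long-lived genes would open more slowly late than early in knockdown. The gap, which is negative as it opens, changed by -0.225 per hour on the log2 scale early and -0.238 late, so it opened slightly faster late. The late minus the early rate was -0.013 (-0.035 to 0.002 without single libraries), and since 1 end of that range lies on the other side of 0, it does not decide. The short-lived and long-lived genes were the 2686 with the largest and the 2686 with the smallest fall in control from 0 to 3.5 h. In control the rates were -0.341 and -0.628, but these libraries chose the genes, so their rates cannot be compared with those in knockdown. A biological narrowing through NAT10 therefore stays a hypothesis beside continued transcription.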

How the results depend on the processing

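Scaling over the ERCC transcripts by TMM, the authors' library factors, the removed GC trend, the lists without knockdown replicate 1 at 0 h, the count filter on control libraries alone for naive markers and the estimated correlation under TMM were tests chosen only after the results were seen. Of the alternative values for the main results 224 stayed within their bounds, 41 moved and 2 reversed. Of those for single genes 2077 stayed, 33 lost their call, 13 gained one and 19 reversed. Unless said, the cause was not tested. By construction, scalings to the typical transcript remove a loss shared by all transcripts. DESeq2's size factors gave 5438 fallen and 5815 risen genes in control, 3746 and 4307 in knockdown and 3049 with slower decay, and TMM gave 5804, 5301, 3814, 4213 and 3439. The median half-life difference reversed to 3.99 h and 4.26 h under these. Left out in turn, single libraries gave -0.991 to -0.33 h. At 0 h, ERCC scaling gave 936 higher and 10748 lower genes, and a fit to the compared groups alone gave 2975 lower. Such a fit does not exist for the slope, which uses all groups.

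Without a filter 2 genes rose in knockdown. With the filter on control libraries alone 3 naive markers rose at 0 h, of the 4 left. The interaction at 1.5 h gave 0 faster genes by edgeR (37 at an unadjusted p under 0.05, 0 by DESeq2) and 4 slower, and the 1.5 and 3.5 h libraries alone gave 4699 faster and 261 slower. A change of at least 1 on the log2 scale left 1539 higher and 427 lower at 0 h, 2262 at 1.5 h, 2963 at 3.5 h, 51 risen in control and, for the slope difference over 3.5 h, 1190 faster, by construction. The authors' half-life ratio moved to a median of -1.02 among ratios of at least 1.5. Lists passing with an estimated correlation were 10 at 0 h, 0 for the slope (0 under TMM) and 0 for the fall in control (9 under TMM).

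Leaving out single libraries gave 735 to 4298 faster genes, 221 to 499 slower, 62 to 130 risen in control and 0 to 1 in knockdown. Faster genes numbered 4298 without control replicate 1 at 0 h, 2796 without knockdown replicate 3 at 0 h, 735 and 990 without control replicates 2 and 3 at 3.5 h, and 909 without knockdown replicate 3 at 3.5 h. Slower genes numbered 232 and 221 without control replicates 1 and 3 at 3.5 h and 266 without knockdown replicate 2 at 3.5 h. Risen genes in control numbered 62 without control replicate 2 at 0 h.

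Single genes reversed as follows. In control over 3.5 h, under DESeq2's size factors and TMM, NAT10 stood at 0.27 and 0.21, POU5F1 at 0.84 and 0.78, ANP32B at 0.66 and 0.60, RPL22 at 0.41 and 0.35, and RPL29 at 0.56 and 0.51, and NDUFA9 at 0.028 under the first. NANOG's slope difference was 0.028 and 0.042 (-0.139 to 0.013 without single libraries). At 0 h NANOG stood at -0.56 under ERCC scaling, where it passed as lower (edgeR, adjusted p = 0.0102), and at -0.029 to 0.188 without single libraries. POU5F1 stood at 0.02 in the compared groups alone (-0.062 to 0.033 without single libraries).

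The replicate number as a block gave 3969 higher and 4733 lower genes at 0 h, 9113 and 10244 changed at 1.5 and 3.5 h, 13509 fallen and 100 risen in control, 16311 and 0 in knockdown, and 1756 faster and 385 slower. The numbers do not pair the samples: 18 of 45 same-numbered pairs correlated above 0.1 (median -0.114), and 5 of 18 libraries correlated best with their own number. Depth differed little between libraries (15037492 to 15519197 counts), while the ERCC share was at most 0.544% of them.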

Other observations

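The genes in this part were set side by side only after their values were seen, and no test was added.

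Transcripts of MT2A, MT1G and MT1X ended the block higher in control than in knockdown, relative to their own 0 h level. They belong to the metallothionein family, whose proteins bind zinc and copper and which was not tested as a list. At 3.5 h MT2A, MT1G and MT1X stood at 126 ± 21.2%, 226 ± 40.8% and 213 ± 39.9% of the 0 h level in control and at 41.8 ± 6.58%, 40.0 ± 5.05% and 38.5 ± 3.08% in knockdown (SD, n = 3 each). The rise of MT2A in control did not pass the test (adjusted p = 0.104). At 0 h MT2A was lower in knockdown (log2 fold change -2.48 ± 0.34), from control libraries that spread widely (72.9 ± 56.9 CPM), while MT1X was higher (2.67 ± 0.178). The family shares near-identical sequence, so its single members are uncertain.

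Mitochondrially encoded transcripts, which are made by a separate polymerase, fell under the block as well. In control 13 of 13 members of their list fell under ERCC scaling, with a median log2 fold change of -1.16 against -1.14 for all genes, while under TMM scaling 5 fell and 2 rose (median -0.03). The list test passed to the lower side (camera adjusted p = 0.0423), but not under TMM scaling (adjusted p = 0.202) or with an estimated correlation (0.69, and 0.543 under TMM scaling). What was left differed between its members. At 3.5 h MT-ND1 was left at 19.5 ± 3.64% in control and 25.1 ± 3.1% in knockdown, MT-ND2 at 20.8 ± 3.99% and 40.5 ± 4.83%, MT-ND6 at 47.4 ± 10.4% and 26.8 ± 3.57%, and MT-CO1 at 57.3 ± 10.7% and 55.2 ± 8.09% (SD, n = 3 each).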
